A study of Arabidopsis thaliana with 60 samples.

How the data were processed

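Leaf RNA of Arabidopsis thaliana was measured on 60 single-colour arrays, 5 in each of 12 groups. The groups form a factorial of inoculation with Pseudomonas aeruginosa strain 7NR (yes or no), UV-B (yes or no) and insect (none, aphids or caterpillars). Each array held RNA pooled from 15 plants of the same tray, harvested at 44 days of age, per the labels. Group and replicate number were taken from the sample titles, because the sample descriptions are less specific. P-values measure the spread between these pools, not between single plants.

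The deposited values are an intensity on a linear scale, one per probe set and array, made with RMA per the submitters' processing notes. The version of RMA, the scanner software and any array filter are not given in the sources used here, and scanner files and detection calls were not used here. The design written beforehand allowed for linear values, so log2 was taken before every fit. All columns belonged to arrays of this series. Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested, with no filter on dim probe sets. No probe set was called present or absent, so a low value may be background.

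Probe sets were named from the platform annotation, updated through Entrez identifiers to the symbols of the RefSeq gene table (assembly TAIR10.1, used for names alone; the files name no genome build, so no coordinates are given). That annotation gave 1 gene to 13513 probe sets, several to 503 and none to 8730. The probe sets with 1 gene stood for 13355 different genes, and 13436 of them matched RefSeq. A symbol other than the locus code was available for 1557 genes, and the others are given by locus code. Probe sets with several genes or none are given by their probe set identifier. For a gene with several probe sets, that of the highest mean over all arrays was used.

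Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a constant prior). A model with a coefficient for each of the 12 groups and the serial run as a fixed block was fitted to all 60 arrays, with 44 residual degrees of freedom and 4.32 prior degrees of freedom. Average effects compared the 20 arrays with caterpillars or the 20 with aphids with the 20 without insects, the 20 with caterpillars with the 20 with aphids, and the 30 arrays with UV-B or with Pseudomonas with the 30 without. The 5 interactions between pairs of treatments, the three-way interaction (an F test) and each treatment alone against untreated plants (5 arrays a side) were contrasts of the same model. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 22746 probe sets of each contrast, with a threshold of 0.05. Levels are means ± SD over arrays on the log2 scale, and differences carry the model's standard error (SE). The run block is additive, so a treatment effect that varies from run to run is not modelled. For genes with such an effect the SE and the adjusted p may be too small. The direction in each run was read from the difference of means within that run.

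The series design states that the 5 replicates were performed in series, each with all conditions, so the replicate number marks a shared run. Deviations from the group means correlated within each run, with median correlations of 0.52, 0.4, 0.11, 0.27 and 0.56 for runs 1 to 5, against -0.12 between arrays of different runs. The run was therefore kept as a block, and the fit without it was an alternative.

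Named genes followed a fixed rule. For the average effects of the treatments it took up to 12 rises and 12 falls, the largest past the threshold with the same sign in all 5 runs, and for caterpillar minus aphid 6 and 6. It also took up to 5 per interaction, 3 rises and 3 falls per treatment alone, up to 4 members of each fixed list past the threshold (or the 2 of largest change), and the marker genes PR1, PDF1.2, VSP2, LOX2, AOS, CHS, HY5, PAD3, MYB51 and CCA1. Of these markers PDF1.2 alone had a named probe set and the others were not analysed here. The comparisons, the rule, the gene lists and the alternatives not marked as later were chosen before the data were examined.

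The 22 fixed lists hold 351 genes, of which 45 had a named probe set, so most lists were measured through a few members. They cover jasmonate synthesis and response, ethylene and ethylene-jasmonate response, salicylate, early wound and immune signalling, aliphatic and indole glucosinolates, flavonoids, UV-B signalling, DNA damage, oxidative stress, heat shock, abscisic acid with cold and drought, senescence, photosynthesis, the circadian clock, auxin, sulfur, phosphate and iron status, and root and flower markers. The 6 lists with at least 3 measured members were tested with limma's camera, with a preset correlation of 0.01 and, as an alternative, an estimated correlation. Counts adjusted over the list alone are given beside those over all probe sets. In the same way 46 families of at least 5 genes sharing a symbol stem or encoded in the plastid, chosen after the values were available, were tested.

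Alternatives were the fit without the run, the run as a random effect, a further quantile normalization, centring each array on its median, leaving out the dimmest 30% of probe sets, array weights, a trended and robust prior, and leaving out each run in turn. Fits of a treatment alone were also run on the 10 arrays compared. After array quality had been seen, 3 more were added, which left out the third array with caterpillars alone, left out the 12 arrays of lowest correlation with the others, or took the GAPDH 5' minus 3' control signal as a covariate. To see what shared controls alone give, residuals of the fit were shuffled within runs 50 times, with both insect effects set against the same arrays labelled as uninfested. A further 20 shuffles used separate uninfested arrays for each insect. The residuals were not scaled up for the coefficients fitted, so their spread is somewhat too small. Regroupings of the arrays, or for interactions shuffles of residuals within runs, numbered 100 per result. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

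The procedure was tested on simulated data built from the real arrays' spread, with 200 of 22746 probe sets changed. Of those changed by 1 on the log2 scale it recovered 97% for the caterpillar effect, 99% for the aphid effect, 99% for caterpillar minus aphid, 99% for UV-B and 100% for Pseudomonas. It recovered from 72% (UV-B by aphid) to 89% (Pseudomonas by UV-B) for interactions between pairs of treatments, 10% for the three-way interaction and from 71% (caterpillar alone) to 82% (aphid alone) for treatments alone. At a change of 0.5 the recovery was 75% for caterpillar, 94% for UV-B, 86% for Pseudomonas, 22% for UV-B by caterpillar and 9% for aphid alone. Each comparison was simulated a single time. Among the unchanged probe sets 50 were called for the aphid effect and 10 for Pseudomonas alone, and from 0 to 5 for the other comparisons. The number of arrays limits the precision.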

Results

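Transcript levels were measured in leaves of Arabidopsis thaliana grown with or without the bacterium Pseudomonas aeruginosa strain 7NR, with or without UV-B, and with aphids, caterpillars of Trichoplusia ni or no insect. Seedlings were inoculated on day 15, received UV-B at 9 kJ per square metre per day for 7 days from day 21 after transplanting, and met insects for 24 hours from day 28. The labels do not name the aphid species or the hour of harvest. All 12 combinations were present with 5 arrays each, made in 5 serial runs, and each array held a pool of 15 plants.

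Array medians lay close together, from 5.09 to 5.39 on the log2 scale, but interquartile ranges differed, from 1.85 to 3.42. The median correlation of an array with the others ranged from 0.763 to 0.98. The lowest belonged to the third array of plants with caterpillars alone, followed by the first array of plants with UV-B and caterpillars at 0.911. Both also had the lowest GAPDH 5' minus 3' control signals, at -4.67 and -4.31 against a median of -1.11 over the 60 arrays. Their Actin 5' minus 3' signals were not low, at -1.06, the highest of the 60, and -3.08 against a median of -3.01. The runs differed in the GAPDH signal, with means of -2.23 ± 0.86 in run 1 and -2.14 ± 1.01 in run 3 against -1.05 ± 0.36, -0.75 ± 0.24 and -0.58 ± 0.29 in runs 2, 4 and 5 (SD, n = 12 arrays each). Neither the 5' minus 3' signals, the spread of values nor the correlation differed with a treatment (lowest adjusted p = 0.66 over 16 sign-flip permutation tests, for the aphid effect on the correlation, 0.00729, and on the Actin signal, -0.17). The leading principal component held 33.3% of the variance, and 57% of it lay between runs. The second held 14.2%, of which 52.6% lay between runs and 22.6% between insect treatments. The third held 8.6%, with 27.7% of it between insect treatments. The fourth held 5.83%, and 55.5% of that lay between insect treatments.

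**Figure D1:**
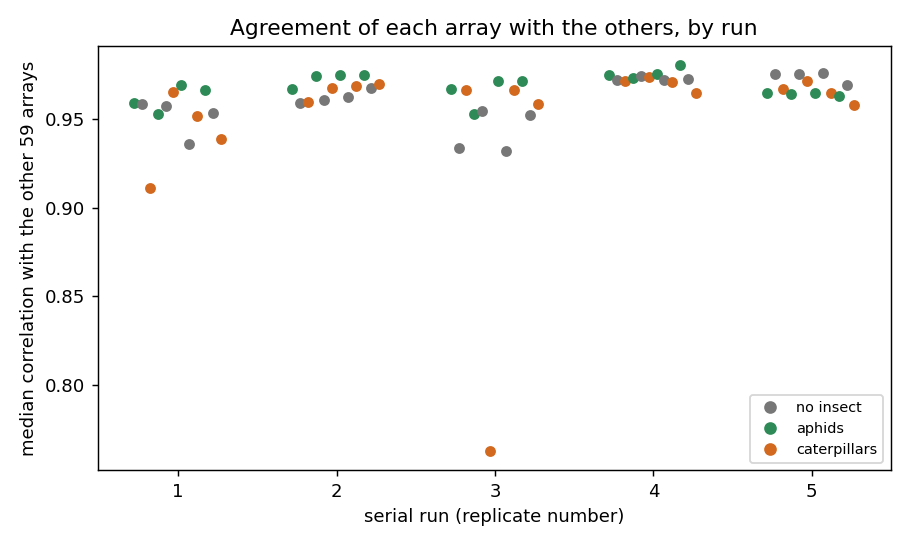
Median Pearson correlation of each array with the other 59 arrays (vertical axis) by serial run (horizontal axis), with a point per array coloured by insect treatment. The third array with caterpillars alone lies at 0.763 and every other array at 0.911 or above.

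Caterpillar feeding was compared with no insect to ask which leaf transcripts respond to chewing. Among probe sets with a named gene and the same sign in 5 of 5 runs, the largest rise was that of JAL23, a jacalin-related lectin, from 4.69 ± 0.53 without insects to 7.73 ± 1.17 with caterpillars (SD, n = 20 arrays each), an 8.22-fold difference (log2 3.04, SE 0.25, adjusted p = 4.6e-13, higher in 5 of 5 runs). AT4G17470 rose 7.2-fold, from a mean of 4.46 to 7.31. The defensin-like genes AT2G43550 and AT2G43530 rose 5.68-fold and 5.11-fold, AT2G43530 from 7.95 ± 0.37 to 10.30 ± 0.66. AT4G24350 (log2 1.93) and AT3G28220 (1.82) came next. Also among the 12 largest rises so defined were the jasmonate-inducible oxygenase genes AT5G05600 (3.5-fold) and JRG21 (2.89-fold), the berberine bridge enzyme-like AT2G34810 (log2 1.63), the strictosidine synthase-like AT3G51450 (1.56), the GDSL lipase-family gene AT1G54020 (1.53) and a further jacalin-related lectin, JAL34 (1.45). All 12 were higher in 5 of 5 runs, with adjusted p of 3.5e-07 or less.

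By the same definition the largest fall with caterpillars was that of AT5G15950, an S-adenosylmethionine decarboxylase gene of polyamine synthesis, from 8.80 ± 1.48 to 7.25 ± 1.51 (log2 -1.55, SE 0.24, adjusted p = 9.7e-06, lower in 5 of 5 runs). AT2G41250 and AT4G39670 were both lower by log2 -1.33. The cycling Dof factor gene AT1G69570 (CDF5) fell from 6.24 ± 1.17 to 5.07 ± 0.53, and AT3G13610, which encodes the feruloyl-CoA hydroxylase of scopoletin synthesis, from 6.76 ± 0.80 to 5.63 ± 0.74. The other falls of this group were AT1G56060 (-1.10), AT3G48640 (-1.07), AT3G48650 (-1.06), the subtilase gene SBT3.3 (-1.05), AT1G68440 (-1.03) and AT5G39670 (-1.01), and AT4G32870 fell to 0.501 of its level. Each was lower in 5 of 5 runs, with adjusted p from 4e-08 to 0.0015. The call of AT3G48650 was lost without run 2 (log2 -0.88).

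Among the hormone lists, jasmonate biosynthesis was measured through OPCL1, a CoA ligase of that pathway, which rose by log2 0.61 (SE 0.11, adjusted p = 6.1e-05, 4 of 5 runs). Both measured members of the ethylene and ethylene-jasmonate list are plant defensins, and both rose: PDF1.2 by 0.78 (SE 0.23, adjusted p = 0.016) and PDF1.2b by 0.64 (SE 0.17, adjusted p = 0.0073), each in 4 of 5 runs. The probe set of PDF1.2b is of a kind that similar transcripts can share, so the 2 defensins may not be separate readings, here and below. Their calls were lost without run 2 (0.70 and 0.62) or run 5 (0.46 and 0.42). These are averages over UV-B and inoculation. In plants given neither, PDF1.2 was not higher with caterpillars, as its group means under the interactions below show. Of the 2 measured salicylate genes, the glutaredoxin gene GRX480 rose by 0.65 (adjusted p = 0.037, 4 of 5 runs) and SAG101 fell to log2 -0.58 (adjusted p = 0.0079, 5 of 5 runs). GRX480 missed the threshold without run 1 (0.61), run 2 (0.43), the third array with caterpillars alone (0.58) or the replicate block (0.65), with the 5' minus 3' covariate (0.56) and with the 12 arrays of lowest correlation left out (0.34), and SAG101 without run 2 (-0.51). In the auxin list GH3.3, which encodes an auxin-conjugating enzyme, rose by 0.53 (adjusted p = 0.035, 3 of 5 runs) and its relative WES1 fell to -0.70 (adjusted p = 0.0011, 5 of 5 runs), with the remaining member not past the threshold. The GH3.3 call was lost without run 2 (0.34), run 4 (0.35), run 5 (0.47) or the replicate block (0.53), and after a further quantile normalization (0.47). Counts adjusted over the list alone were the same in these 4 lists, as they were for the glucosinolate, clock, UV-B, early wound and root lists below.

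Of 5 measured flavonoid and anthocyanin genes 3 rose, with 3 adjusted over the list alone. DFR, the dihydroflavonol reductase of anthocyanin synthesis, was higher by 1.25 (2.37-fold, SE 0.21, adjusted p = 3.1e-05, 5 of 5 runs), and the glycosyltransferase genes UGT78D1 by 0.85 (adjusted p = 0.001) and AT4G14090 (UGT75C1) by 0.51 (adjusted p = 0.0014), each in 4 of 5 runs. The list's median was 0.51, with a camera adjusted p of 0.022, but an adjusted p of 0.27 with an estimated correlation. That call was lost without run 1 (median 0.62), run 2 (0.31) or run 3 (0.43), and those of UGT78D1 (0.50) and AT4G14090 (0.31) without run 2. Both measured aliphatic glucosinolate genes rose, BCAT4 by 0.82 (adjusted p = 0.0019, 5 of 5 runs) and AT2G31790 (UGT74C1) by 0.60 (adjusted p = 0.0036, 4 of 5 runs). UGT74B1, 1 of 2 measured in the indole list, rose by 0.48 (adjusted p = 0.035, 4 of 5 runs). Leaving out run 2 ended the calls of BCAT4 (0.52), AT2G31790 (0.37) and UGT74B1 (0.35), and that of UGT74B1 was also lost without run 1 (0.43), run 4 (0.56) or the replicate block (0.48).

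GI, a gene of the circadian clock and of flowering time and the measured member of the clock list, rose from 5.90 ± 1.19 to 7.27 ± 0.73 (log2 1.37, SE 0.15, adjusted p = 3.3e-09, 5 of 5 runs). HYH, the bZIP paralogue of HY5 in the UV-B list, fell from 7.00 ± 1.32 to 5.91 ± 1.52 (log2 -1.09, SE 0.19, adjusted p = 6.3e-05, 4 of 5 runs), and this call was lost without the replicate block (adjusted p = 0.11). The HYH difference varied widely between runs, at 0.03, -1.23, -1.04, -2.63 and -0.57 in runs 1 to 5. The other UV-B member did not pass. Of 3 measured early wound and immune genes WRKY6 fell to -0.39 (adjusted p = 0.021, 5 of 5 runs). The WRKY6 call was lost without run 1 (-0.36), run 2 (-0.31) or the replicate block (-0.39) and after a further quantile normalization (-0.33), and camera gave the list an adjusted p of 0.2. PYK10, an endoplasmic reticulum body β-glucosidase that stands in the root marker list, rose by 1.21 (SE 0.25, adjusted p = 0.00061, 5 of 5 runs), while the root hair expansin EXPA7 did not pass. No measured member passed in heat shock (4), abscisic acid, cold and drought (3), senescence (1), photosynthesis (10), sulfur (1) or flower markers (1). Camera adjusted p were 0.81 for heat shock, 0.34 for abscisic acid, 0.43 for photosynthesis and 0.67 for auxin. In the sulfur list BGLU28, at 0.12, passed when adjusted over the list alone, and without run 3 over all probe sets (0.17). Without run 3 LHCB4.2 also passed (-0.24), and without run 4 AT5G48570 (ROF2) of the heat shock list did (1.89). COR15A and COR47 of the abscisic acid list passed with the 12 arrays of lowest correlation left out (0.63 and 0.56). The lists of jasmonate response, DNA damage, oxidative stress, phosphate and iron had 0 measured members in every comparison.

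Over all probe sets, 3061 passed the threshold with caterpillars, 1114 higher and 1947 lower, and 169 of them differed at least 2-fold. The count was 1391 without the replicate block, 884 without run 2 and 4979 without run 3.

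**Figure D2:**
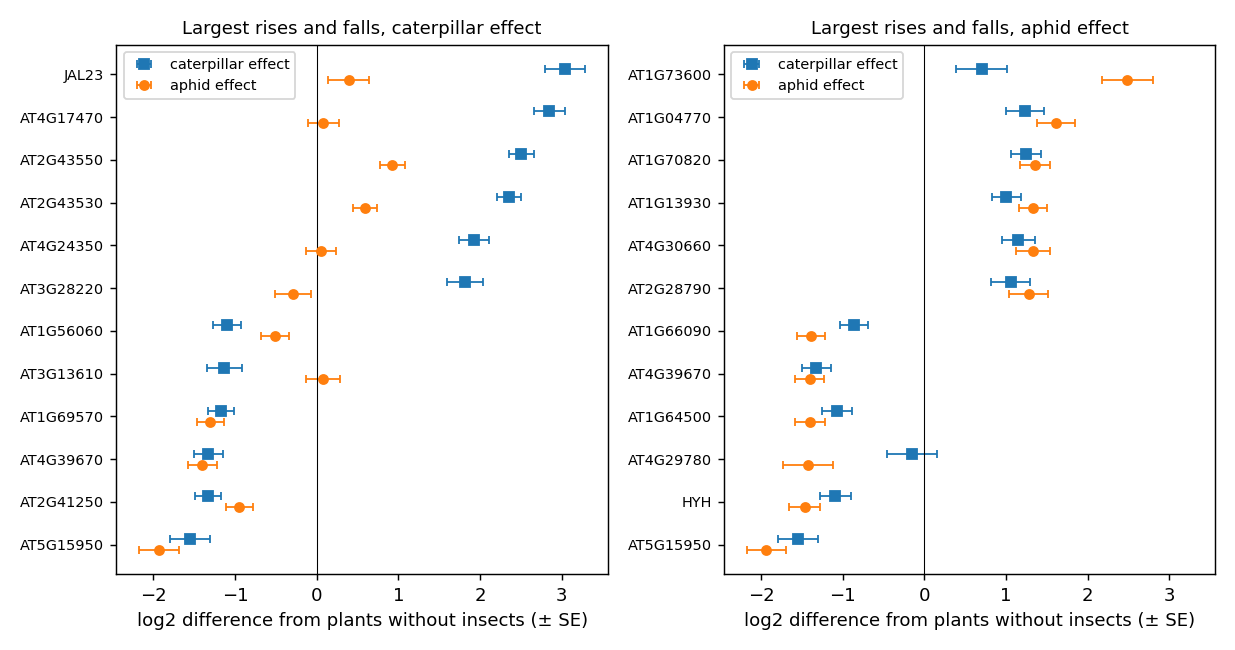
Log2 difference from plants without insects (horizontal axis, ± SE, 20 arrays a side) for 6 of the largest rises and 6 of the largest falls with caterpillars (left) and with aphids (right), each gene shown for both insects. JAL23 stands at 3.04 with caterpillars and 0.39 with aphids, and AT5G15950 at -1.55 and -1.93.

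Aphid feeding was set against no insect to ask the same of a phloem-feeding insect. Among probe sets with a named gene and the same sign in 5 of 5 runs AT1G73600, a phosphoethanolamine methyltransferase gene of phospholipid synthesis, rose most, from 6.65 ± 1.95 to 9.14 ± 0.73 (5.59-fold, log2 2.48, SE 0.31, adjusted p = 2.1e-07, 5 of 5 runs). Its level in uninfested plants differed between runs, at 5.39, 5.18, 5.20, 7.85 and 9.66 in runs 1 to 5 (means of 4 arrays), and its aphid difference was 2.86, 4.17, 3.71, 1.38 and 0.30. AT1G04770 rose 3.04-fold, AT1G70820 2.55-fold and AT1G13930 2.52-fold. The low-temperature and salt-responsive small membrane protein genes AT4G30660 (1.33) and AT4G30650 (1.03) were among the 12 largest rises so defined, with AT2G28790 (1.28), the subtilase-family gene AT5G45650 (1.18), the pentatricopeptide repeat gene PPR596 (2.14-fold), the β-glucosidase gene BGLU44 (1.06), AT4G26130 (1.02) and AT1G01300 (0.98). These 12 were higher in 5 of 5 runs, with adjusted p of 0.0011 or less. Without the replicate block BGLU44 (adjusted p = 0.085) and AT4G30650 (adjusted p = 0.11) missed the threshold.

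AT5G15950 was also the largest fall with aphids by that definition, from 8.80 ± 1.48 to 6.87 ± 0.90 (log2 -1.93, SE 0.24, adjusted p = 2.1e-07, 5 of 5 runs), followed by HYH, at 5.54 ± 0.93 with aphids (log2 -1.47, SE 0.19, adjusted p = 4.3e-07, 5 of 5 runs). AT4G29780 (-1.42), AT1G64500 (-1.41), AT4G39670 (-1.40), the TIR-NBS resistance-type gene AT1G66090 (-1.39), AT1G19020 (-1.34), the trichome birefringence-like gene TBL37 (-1.30), AT1G69570 (-1.30), AT3G02840 (-1.27), AT1G68440 (-1.25) and AT3G15310 (-1.24) completed the 12. All fell in 5 of 5 runs, with adjusted p from 3.4e-09 for AT1G19020 to 0.00076 for AT4G29780.

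All 3 measured genes of early wound and immune signalling fell with aphids, with 3 adjusted over the list alone. The zinc finger gene STZ was lower by log2 -1.04 (SE 0.23, adjusted p = 0.00081), WRKY53 by -0.80 (SE 0.21, adjusted p = 0.0055) and WRKY6 by -0.65 (SE 0.12, adjusted p = 0.00011), each in 5 of 5 runs. The list's median was -0.80, with a camera adjusted p of 0.00029 and an adjusted p of 0.033 with an estimated correlation. At the preset correlation, 1 or more fixed lists passed in 63 of 100 regroupings of the arrays, the real one included. The 0.00029 may therefore be too small. WRKY53 missed the threshold without run 2 (-0.69). Of 3 auxin genes WES1 fell to -0.64 (adjusted p = 0.0023) and GH3.3 to -0.52 (adjusted p = 0.035), each in 4 of 5 runs, and 2 fell adjusted over the list alone. WES1 lost its call without run 2 (-0.50), and GH3.3 without run 1 (-0.32), run 2 (-0.55), run 3 (-0.43) or the replicate block (-0.52). Camera gave the auxin list an adjusted p of 0.075, and 0.026 without run 4 (median -0.66).

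GI rose with aphids too, by 0.81 (SE 0.15, adjusted p = 0.00016, 4 of 5 runs), a call lost without the replicate block (adjusted p = 0.11). Its aphid difference was 1.64, 1.21, 0.87, -0.61 and 0.93 in runs 1 to 5. In the aliphatic glucosinolate list AT2G31790 rose by 0.59 (adjusted p = 0.0035, 4 of 5 runs) and BCAT4 passed only when adjusted over the list alone, which gave 2. The AT2G31790 call was lost without run 1 (0.45) or run 2 (0.40). UGT74B1 of the indole list, at 0.39 (adjusted p = 0.088), passed over the list alone, and over all probe sets without run 5 (0.56), without the third array with caterpillars alone (0.39) or after a further quantile normalization (0.42). In the flavonoid list UGT78D2 fell to -0.53 (adjusted p = 0.012, 4 of 5 runs), 1 of 5 members on both counts, and the call was lost without run 2 (-0.53), run 3 (-0.38) or the replicate block (-0.53). The camera adjusted p of that list was 0.94. AT5G48570 (ROF2), an FKBP-type co-chaperone and 1 of 4 heat shock genes, rose by 1.76 (SE 0.50, adjusted p = 0.011) in 3 of 5 runs, and not without run 1 (1.13), run 2 (1.26) or run 3 (1.42), nor with the 12 arrays of lowest correlation left out (0.996). The heat shock list had a camera adjusted p of 0.3, and of 0.029 without run 4 (median 0.36). PYK10 stood at 0.65 (adjusted p = 0.074), past the threshold over the root list alone and, without run 5, over all probe sets (0.92). OPCL1 (0.09), PDF1.2 (-0.12), PDF1.2b (-0.06), GRX480 (0.24) and SAG101 (-0.19) did not pass, nor did any measured member of abscisic acid (camera adjusted p = 0.35), photosynthesis (0.81), senescence, sulfur or flower markers.

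With aphids 3363 probe sets passed, 1643 higher and 1720 lower, of which 162 differed at least 2-fold. There were 1771 without the replicate block, 2077 without run 1 and 913 without run 2. Control probe sets were also higher with aphids, by 0.59 (SE 0.16, adjusted p = 0.0075) for the middle and 0.43 (SE 0.08, adjusted p = 9.4e-05) for the 3' end of Actin, and by 0.26 (SE 0.07, adjusted p = 0.0057) for the 3' end of GAPDH.

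**Figure D3:**
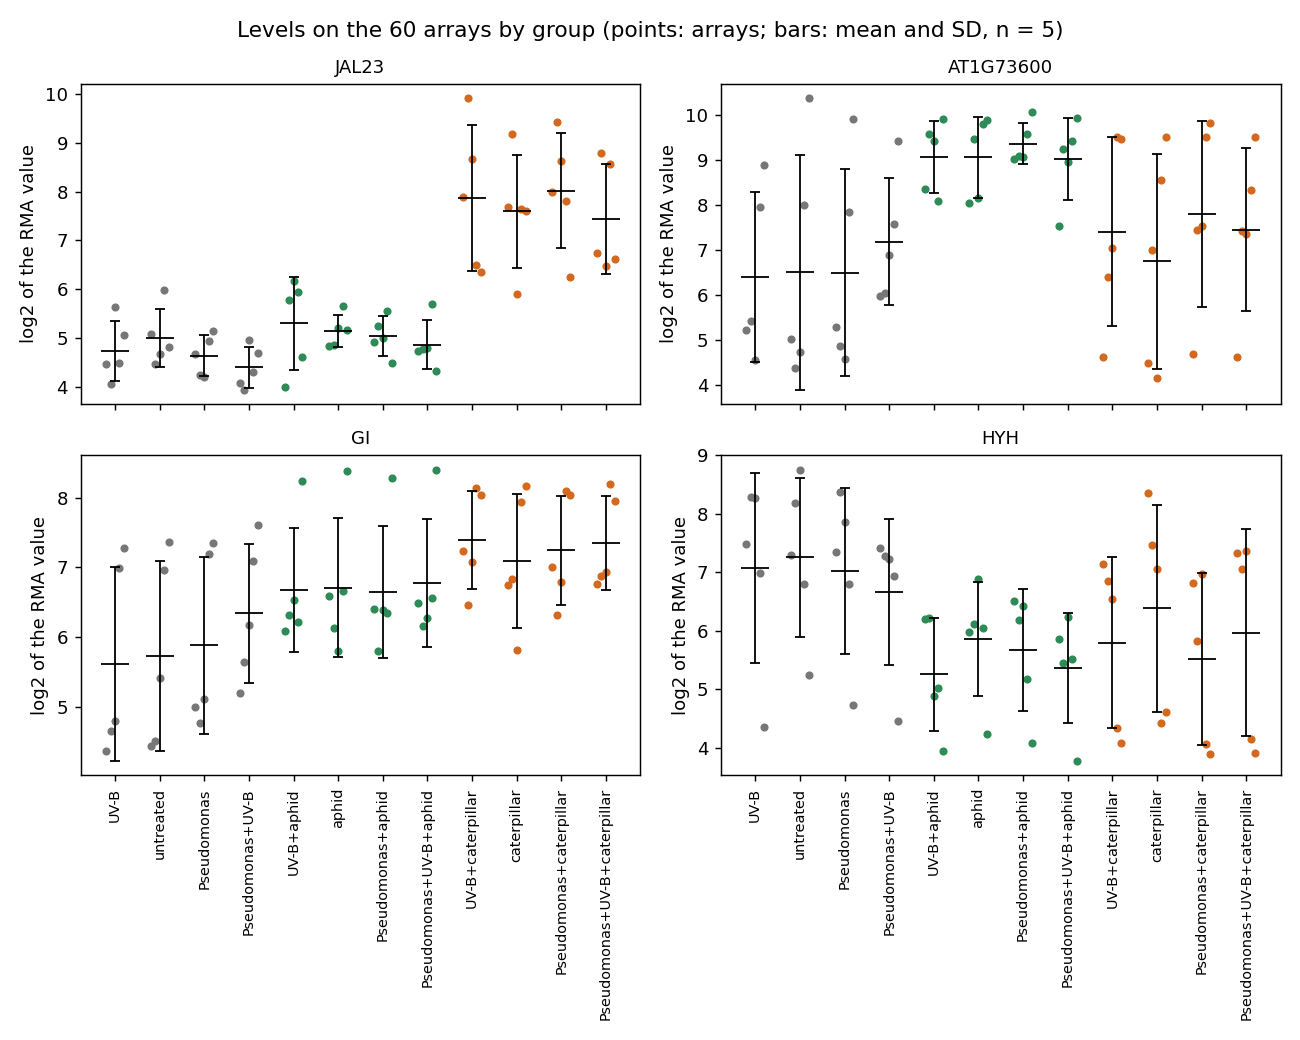
Log2 level of JAL23, AT1G73600, GI and HYH (vertical axes) on each array of the 12 groups (horizontal axis), with bars for the mean and SD (n = 5 arrays a group). JAL23 is high with caterpillars under every combination of UV-B and Pseudomonas, and the levels of GI and HYH spread widely between the runs of a group.

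Plants with caterpillars and plants with aphids were then compared directly. The largest differences were again taken among named genes chosen for the same sign in 5 of 5 runs. AT4G17470 was 6.8-fold higher with caterpillars (log2 2.77, SE 0.19, adjusted p = 1.4e-15), JAL23 6.26-fold, JRG21 4.64-fold, AT3G28220 4.33-fold, AT5G05600 4.24-fold and AT4G24350 3.66-fold, each in 5 of 5 runs. JRG21 itself fell with aphids against no insect (log2 -0.68, adjusted p = 0.016). Higher with aphids were AT3G28510 (log2 -1.96, adjusted p = 3.9e-06), which rose by 1.77 (adjusted p = 2e-05) with aphids against no insect, AT1G73600 (-1.78, adjusted p = 7.9e-05), UGT76B1, a glucosyltransferase gene of isoleucic acid (-1.76, adjusted p = 4.9e-05), AT4G29520 (-1.31), AT1G19960 (-1.30) and the small heat shock protein gene AT2G29500 (-1.30, adjusted p = 0.015), all in 5 of 5 runs. The last of these was lost without run 1 (-1.18), run 2 (-1.30) or run 4 (-1.24).

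The difference between the insects passed for OPCL1 (0.52, adjusted p = 0.00072, 5 of 5 runs), PDF1.2 (0.89, adjusted p = 0.0075, 4 of 5 runs) and PDF1.2b (0.70, adjusted p = 0.0047, 5 of 5 runs), though for the defensins not without run 1 (0.71 and 0.56) or run 2 (0.76 and 0.64). GH3.3, which moved in opposite directions with the 2 insects, differed by 1.05 (SE 0.17, adjusted p = 3.4e-05, 5 of 5 runs). GI was higher with caterpillars by 0.57 (adjusted p = 0.012, 4 of 5 runs), but not without run 2 (0.58), run 4 (0.30) or the replicate block (adjusted p = 0.37). For HYH the difference was 0.38 (adjusted p = 0.22), and it passed without run 4 (0.77). In the flavonoid list 2 of 5 were higher with caterpillars (4 adjusted over the list alone), DFR by 0.96 (adjusted p = 0.0016, 5 of 5 runs) and AT4G14090 by 0.47 (adjusted p = 0.0051, 5 of 5 runs), the latter lost without run 2 (0.29). The list's median was 0.45, with a camera adjusted p of 0.0071 and an adjusted p of 0.16 with an estimated correlation, and without run 2 it missed the threshold (0.28). Of the early wound genes STZ differed by 0.90 (adjusted p = 0.0062, 5 of 5 runs), and 3 did over the list alone. The median was 0.44 (camera adjusted p = 0.041, adjusted p = 0.25 with an estimated correlation), past the threshold neither without run 1 (0.37), run 2 (0.38) nor run 4 (0.31), and STZ behaved alike (0.82, 0.84 and 0.68).

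BGLU28 of the sulfur list was higher with caterpillars by 0.17 (adjusted p = 0.041, 5 of 5 runs), a call lost without run 1 (0.13), run 2 (0.18), run 4 (0.16), the third array with caterpillars alone (0.15) or the replicate block (0.17), and after a further quantile normalization (0.10). Of the salicylate genes 0 passed over all probe sets and SAG101, at -0.40, did over the list alone; GRX480 (0.41) passed without run 3 (0.55). Counts were 0 in the glucosinolate, UV-B, heat shock (camera adjusted p = 0.26), abscisic acid (0.8), senescence, photosynthesis (0.22), root and flower lists, and auxin had a camera adjusted p of 0.22. In all 2141 probe sets differed, 806 higher and 1335 lower with caterpillars, with 926 without the replicate block, 1005 without run 1 and 632 without run 2.

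The calls for caterpillars and for aphids were set against each other. Of the probe sets past the threshold, 401 were higher and 893 lower with both insects, against 80.5 and 147 for independent lists, and 22 had opposite signs. Fold changes correlated across probe sets at 0.541, while residuals shuffled within runs, with shared uninfested arrays, gave a simulated mean of 0.481 (SD 0.18). The covariance was 0.0331 against a simulated 0.00435 (SD 0.0028). The shuffles gave a mean of 0.06 calls for caterpillars and 0.04 for aphids, so they give no value to set beside the 401 and 893. Shuffling also removes an offset common to the uninfested plants of a run, so such an offset was not tested. With separate uninfested arrays for each insect the correlation was 0.237 (simulated -0.00518, SD 0.27) and the covariance 0.0192 (simulated SD 0.005), with 51 higher, 183 lower and 4 opposite, against 18.8 and 32.5 for independent lists. The share of probe sets with the same sign in both effects was 64.6% (simulated 66.1%, SD 8.4), and 46.5% with separate uninfested arrays (simulated 50%, SD 10). Probe sets are not independent replicates.

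Plants given UV-B for 7 days were compared with plants without it, over all insect and bacterial treatments. The clearest difference was at AT2G07718, whose probe set is of the kind that several transcripts can share and which fell from 5.55 ± 0.34 to 4.96 ± 0.33 (SD, n = 30 arrays each, log2 -0.59, SE 0.07, adjusted p = 1.5e-07, 5 of 5 runs). AT1G22690 (0.53, adjusted p = 0.017), AT3G62820 (0.51, adjusted p = 0.0023) and AT5G25840 (0.47, adjusted p = 0.017) rose, each in 5 of 5 runs. The remaining calls, named after their values were seen, had no named gene: 259224_at (0.39) and 248668_at (0.39) were higher, 250983_at (-0.44) and 267567_at (-0.64) lower, in 5 of 5 runs with adjusted p from 0.0087 to 0.0092. PDF1.2 (-0.67, adjusted p = 0.33, 5 of 5 runs) and PDF1.2b (-0.54, adjusted p = 0.24, 4 of 5 runs) passed over the list alone and not over all probe sets. HYH stood at -0.26 (adjusted p = 0.87), and 0 members of any fixed list passed over all probe sets. Camera adjusted p were 0.8 for early wound genes, 0.94 for flavonoids, 0.31 for heat shock, 0.16 for abscisic acid, 0.17 for photosynthesis and 0.8 for auxin, and without run 5 both abscisic acid (median 0.25) and photosynthesis (0.07) passed, each with 0.035. In all 8 probe sets passed, 5 higher and 3 lower, by limma, with 1260 at an unadjusted p under 0.05. A further quantile normalization gave 5 and 5, and centring on the median 5 and 6. By chance alone about 5% of the 22746 probe sets would have an unadjusted p under 0.05, here and below. There were 4 calls without the replicate block, 3 without run 2, 4 without run 3, 1 without run 4 and 3 without run 5. AT1G22690 was lost without any of runs 1 to 5 (0.55, 0.58, 0.34, 0.56 and 0.62), AT3G62820 without run 3 (0.48) or 4 (0.47), and AT5G25840 without the replicate block (0.47) or run 2 (0.44), 3 (0.38), 4 (0.46) or 5 (0.53).

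Inoculated plants were compared with the others to ask whether the bacterium left a mark on leaf transcripts. The 5 probe sets that passed all rose, in 5 of 5 runs: 253872_at by log2 1.12 (2.18-fold, SE 0.18, adjusted p = 0.0028), AT2G25735 by 0.87 (SE 0.17, adjusted p = 0.024), 245276_at by 0.71 (adjusted p = 0.039), 257022_at by 0.51 (adjusted p = 0.024) and AT1G63720 by 0.29 (adjusted p = 0.024). Those without a named gene were named after their values were seen. The list of early wound and immune genes, measured through 3 of 18 members, had a median of 0.44 over WRKY53 (0.75, SE 0.17, adjusted p = 0.073), STZ (0.44, SE 0.18, adjusted p = 0.73) and WRKY6 (0.40, SE 0.10, adjusted p = 0.095). Its camera adjusted p was 6.6e-09, and the adjusted p was 0.00044 with an estimated correlation. Singly, 0 members passed over all probe sets and 3 did over the list alone, and WRKY53 passed with the dimmest probe sets left out. At the preset correlation, 2 or more fixed lists passed in 22 of 100 regroupings of the arrays, the real one included. The 6.6e-09 may therefore be too small. The photosynthesis list of 10 genes had a median of 0.08 and a camera adjusted p of 0.0078, but an adjusted p of 0.33 with an estimated correlation, and it missed the threshold without run 3 (0.02) or the third array with caterpillars alone (0.01), after a further quantile normalization (0.02) and with the 5' minus 3' covariate (0.02). With the 12 arrays of lowest correlation left out its median was -0.0044, and with array weights it was -0.000718.

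No member of the other lists passed after inoculation, over all probe sets or over the list alone. Camera adjusted p were 0.055 for abscisic acid, 0.087 for flavonoids, 0.57 for heat shock and 0.3 for auxin. Without run 4 abscisic acid (0.15) and flavonoids (-0.12) passed, each with 0.04, and abscisic acid also without run 5 (0.22). At an unadjusted p under 0.05 there were 1239 probe sets. The count of 5 became 1 without the replicate block, 0 without run 2, run 3 or run 4, and 2 without run 5. AT2G25735 was lost without the block (0.87) or any of runs 1 to 5 (0.90, 0.86, 0.78, 0.91 and 0.92), and so was AT1G63720 (0.29, and 0.26, 0.31, 0.24, 0.32 and 0.31).

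**Figure D4:**
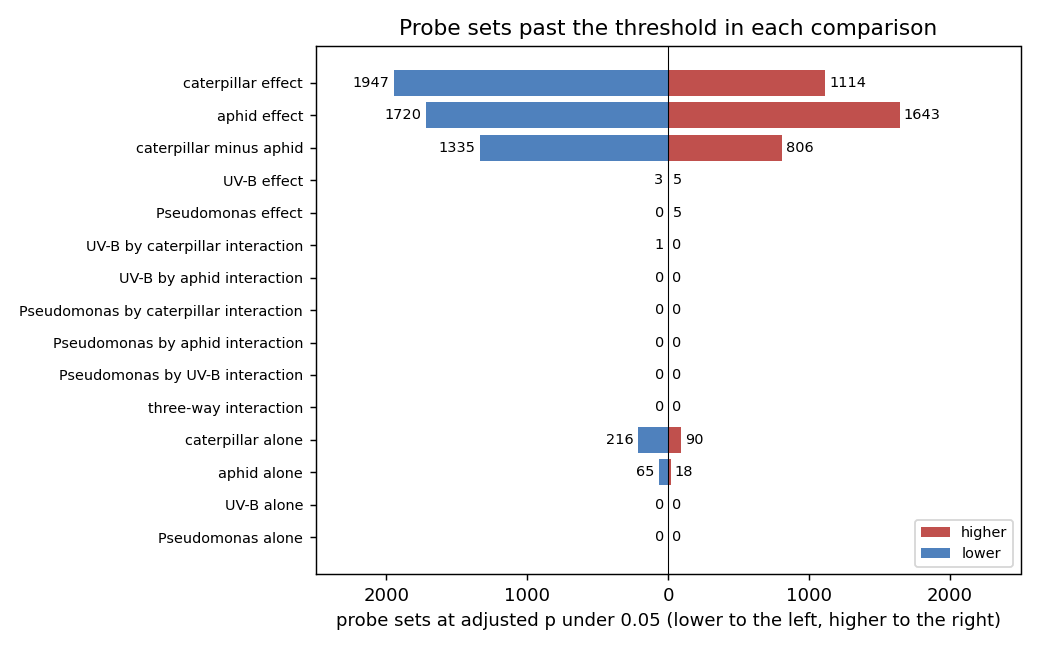
Probe sets past an adjusted p of 0.05 in each of 15 comparisons (horizontal axis, lower to the left and higher to the right). The 3 insect comparisons hold 3061, 3363 and 2141 probe sets, and UV-B and Pseudomonas 8 and 5.

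Interactions asked whether a treatment changed the response to another. The 1 probe set past the threshold was 253046_at, which has no named gene and was named after its values were seen, for UV-B by caterpillar (log2 -1.50, SE 0.27, adjusted p = 0.033, 5 of 5 runs). Without Pseudomonas 253046_at stood at 7.70 ± 0.82 untreated, 7.16 ± 0.88 with caterpillars, 7.79 ± 0.97 with UV-B and 6.64 ± 0.78 with both. In inoculated plants 253046_at was at 7.66 ± 0.80 without other treatments, 7.75 ± 1.37 with caterpillars, 8.66 ± 0.88 with UV-B and 6.37 ± 0.79 with both (SD, n = 5 arrays each). The call was lost without the replicate block and without run 1, 2, 4 or 5, each leaving 0 calls, and without run 3 the 1 call was another probe set. PDF1.2 had group means of 10.72 ± 0.33 untreated, 9.14 ± 0.84 with UV-B, 10.61 ± 0.98 with caterpillars and 10.94 ± 0.53 with UV-B and caterpillars, and its interaction did not pass. By limma 0 probe sets passed for UV-B by aphid (484 at an unadjusted p under 0.05), Pseudomonas by caterpillar (2271), Pseudomonas by aphid (771), Pseudomonas by UV-B (488) and the three-way interaction (622).

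Each treatment alone was also set against untreated plants, 5 arrays a side. With caterpillars alone AT4G17470 rose by 2.79 (SE 0.37, adjusted p = 9.5e-06), JAL23 by 2.60 (SE 0.50, adjusted p = 0.0038) and AT2G43530 by 2.26 (SE 0.29, adjusted p = 7.7e-06), in 5 of 5 runs, and JAL23 was lost without run 2 (2.07). Among the falls were AT2G41250 (-1.59, adjusted p = 0.0084, 5 of 5 runs), AT1G69570 (-1.39, adjusted p = 0.025, 4 of 5 runs) and AT1G64500 (-1.37, adjusted p = 0.045, 4 of 5 runs). All of these falls were lost without the replicate block, without run 2 (-1.50, -1.13 and -1.37) or without the third array with caterpillars alone (-1.32, -1.43 and -0.98), AT1G69570 also without run 3 (-1.23), and AT1G64500 without run 3 (-0.80) or run 4 (-1.26) and after a further quantile normalization (-1.30). The 306 calls were 90 higher and 216 lower, but 86 and 58 after a further quantile normalization and 57 and 6 without the third array with caterpillars alone. There were 25 without the replicate block, 1200 without run 1, 20 without run 2 and 63 without run 3.

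Aphids alone gave 83 calls, 18 higher and 65 lower, or 29 and 50 after a further quantile normalization. AT1G73600 rose by 2.56 (SE 0.63, adjusted p = 0.045, 4 of 5 runs), AT1G70820 by 1.53 (adjusted p = 0.039, 5 of 5 runs) and AT1G13930 by 1.45 (adjusted p = 0.045, 5 of 5 runs). AT5G15950 fell to -2.12 (adjusted p = 0.034), AT1G64500 to -1.91 (adjusted p = 0.018) and AT4G39670 to -1.64 (adjusted p = 0.029), each in 5 of 5 runs. Every one of these calls was lost without the replicate block and without run 1, 2 or 3, each leaving 0 calls, with values between 1.93 and 2.45 for AT1G73600, 1.33 and 1.64 for AT1G70820, 1.15 and 1.47 for AT1G13930, -2.30 and -1.76 for AT5G15950, -1.94 and -1.64 for AT1G64500 and -1.58 and -1.35 for AT4G39670 in those runs' absence. AT1G73600 (2.76) and AT1G13930 (1.64) were lost without run 4 too. There were 335 calls without the third array with caterpillars alone and 636 without run 5. By limma 0 probe sets passed for UV-B alone (409 at an unadjusted p under 0.05) and for Pseudomonas alone (1182). Fits to the 10 arrays compared gave 0 for caterpillars alone and for aphids alone (762 and 2496 at an unadjusted p under 0.05).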

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

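The test of RNA quality on the third array with caterpillars alone and the sign-flip test of the 7 signalling genes were chosen after their results were seen.

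The third array of plants with caterpillars alone stood apart. Its median correlation with the other arrays was 0.7629 (nearest of its group 0.9654) and its interquartile range 1.849 on the log2 scale (nearest 2.952), each a gap of most of its group's range. Its GAPDH 5' minus 3' signal of -4.67 was the lowest of the 60 (the next was -4.31, the median of the others -1.1), but its Actin 5' minus 3' signal of -1.056 was the highest (the next was -2.296, the median -3.013), so the controls point in opposite directions and degraded or poorly copied RNA stays open. Its highest correlation with any array was 0.842, below the lowest median of the others, 0.911, which argues against a wrong label or a swap within the series as the reason it stood apart. Biological causes particular to that pool were not tested.

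The first array of plants with UV-B and caterpillars had a median correlation of 0.9112 (nearest of its group 0.9596), an interquartile range of 2.343 (nearest 2.992) and a GAPDH 5' minus 3' signal of -4.314 (nearest -1.449), with an Actin signal of -3.077 near the median. Of 48 tests, each of 1 group and 1 measure (median correlation, interquartile range, GAPDH 5' minus 3' signal or PDF1.2 level), 5 found such a sample. Chance gives about 1 in 20 in a single test, but the 5 come from these 2 arrays and from measures that depend on each other, so the number is no measure of an excess. The effect of caterpillars on 253046_at differed between plants with and without UV-B (log2 -1.5, adjusted p = 0.033). Among the control probe sets, which belong to no comparison, an Actin 3' probe set was higher with aphids by 0.433 (adjusted p = 9.4e-05), a further Actin 3' probe set by 0.48 (adjusted p = 0.0022), a GAPDH 3' probe set by 0.256 (adjusted p = 0.0057) and a middle Actin probe set by 0.587 (adjusted p = 0.0075).

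GI was higher and HYH lower with either insect, while their levels in uninfested plants differed between runs, from 4.76 to 7.40 for GI and from 4.70 to 8.03 for HYH. The prediction written beforehand was that a harvest of infested plants at a later clock phase would raise evening genes as a set. That direction holds only for a harvest before the peak of these genes, which the labels do not show, so the test cannot decide. The mean of COR27 and COR28 was -0.362 (SE 0.12) with caterpillars and -0.493 (SE 0.12) with aphids, from COR27 (-0.783 and -1.03), as COR28 did not pass (0.06, adjusted p = 0.61, and 0.04, adjusted p = 0.85). The mean did not rise, but 2 of 14 evening genes and 0 of 20 morning genes were measured, and COR27 alone moved. The cycling Dof factor gene AT1G69570 fell with both insects (-1.17 and -1.30) and was not part of this test. A later phase, an earlier phase and a response to feeding therefore stay open, as the hour of harvest is not given. With separate uninfested arrays for each insect the smallest size over SE was 2.91 (GI 1.18 and 0.91, HYH -0.79 and -1.59), which argues against noise in shared control arrays as the source. Both sets of controls come from the same runs. An offset common to the uninfested plants of a run was therefore not tested.

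In inoculated plants 7 genes of early signalling and the WRKY family had a mean log2 difference of 0.305 (SE 0.07), between 0.201 and 0.456 in the 5 runs, carried by WRKY53 (0.75), STZ (0.44), WRKY22 (0.42) and WRKY6 (0.40) and not by WRKY20 (-0.05), WRKY42 (0.07) or WRKY47 (0.12), with 0 past the threshold singly. With the GAPDH 5' minus 3' signal as a covariate it was 0.298 (SE 0.07), which argues against RNA quality as far as that signal measures it, and its lowest value with a run left out was 0.267, which argues against a single run. It was positive in 22 of 30 within-run differences (sign-flip permutation p = 0.00028), on families chosen because they showed the pattern. With aphids the mean was -0.468 (SE 0.09), from falls of WRKY53, WRKY6, STZ and WRKY22, while WRKY20, WRKY42 and WRKY47 did not pass. An effect of the bacterium on these 7 genes was not tested on other data and stays open.

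Other splits of the arrays, 100 for each result with the real one included, were counted to see whether chance gives as many calls. For the insect effects 1 split, the real one, gave as many, with 3061 for caterpillars against a highest other of 2116, 3363 for aphids against 1680 and 2141 for caterpillar minus aphid against 222. UV-B (8 against 1) and Pseudomonas (5 against 1) likewise had 1 split of 100. The labels compared were exchanged within runs, so 1 split of 100, the real one, argues against chance for these 5 without excluding it. For interactions a split was instead a shuffle, within runs, of the residuals of the fit without the tested term. For UV-B by caterpillar 2 splits of 100, the real one among them, gave as many as the 1 call, and the other gave 23. Where 0 calls were made every split gives as many, so the 100 of 100 tests nothing, for UV-B by aphid (highest other 0), Pseudomonas by caterpillar (2), Pseudomonas by aphid (1), Pseudomonas by UV-B (1), the three-way interaction (1), UV-B alone (983) and Pseudomonas alone (423). For caterpillars alone 4 splits gave as many as 306, with a highest other of 6236, and for aphids alone 3 gave as many as 83, with a highest other of 574. Values so far above the real counts point to a structure of the samples, and most of these splits ignore the run. Of the 16 splits with 1 array of each run on each side, 2 gave as many for aphids alone, 1 of them the one with 574, so chance was not excluded within runs. For caterpillars alone 1 of the 16, the real one, did (highest other 275), and 16 splits are too few for a share under 0.05.

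Chance was not excluded for the number of fixed lists past the threshold. It was 1 for caterpillars (67 splits, highest other 5), 1 for aphids (63, 3), 2 for caterpillar minus aphid (17, 4) and 2 for Pseudomonas (22, 4). For UV-B it was 0, where 100 of 100 splits (highest other 3) again tests nothing.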

How the results depend on the processing

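Leaving out the third array with caterpillars alone or the 12 arrays of lowest correlation, and the 5' minus 3' covariate, were chosen after array quality was seen. Of 214 values of named genes (113 past the threshold) 0 reversed under any alternative, and of 30 values of lists (6 past it) 1 did. A change of sign counted as a reversal only where the value passed the threshold before or after it. The largest rises and falls of the average effects were chosen for the same sign in all 5 runs. Leaving out a run could therefore not reverse them. A further quantile normalization left 208 gene values on their side of the threshold, centring on the median 211, array weights 202, a trended and robust prior 214, the covariate 211 and leaving out the 12 arrays 191. The trended and robust prior and centring on the median moved no total count of calls by over 1.5 times, but centring turned the UV-B calls from 5 higher and 3 lower to 5 and 6. Where a value below differs from the report's, the cause was not tested, except that settings with fewer arrays have less precision.

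Without the replicate block, in place of the paired fit, 1391 probe sets passed for caterpillars, 1771 for aphids, 926 for caterpillar minus aphid, 4 for UV-B, 1 for Pseudomonas, 0 for UV-B by caterpillar, 25 for caterpillars alone and 0 for aphids alone, 24 named gene values lost their call, and no call of a fixed list changed. Plastid-encoded genes lower with aphids then numbered 15. Control probe sets and the camera tests of families were not fitted without it. With the replicate block as a random effect there were 3 for Pseudomonas, 0 for UV-B by caterpillar and 33 for aphids alone. Fits with the replicate block to the 10 arrays compared gave 0 for caterpillars alone and 0 for aphids alone.

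A further quantile normalization gave 8 for Pseudomonas, 0 for UV-B by caterpillar and 144 for caterpillars alone, with 1 list past the threshold for Pseudomonas. Array weights gave 4955 for caterpillars, 3405 for caterpillar minus aphid, 18 for UV-B, 10 for Pseudomonas, 2 for UV-B by caterpillar and 98 for caterpillars alone, with 0 lists for caterpillars and 1 for Pseudomonas. Leaving out the dimmest 30% of probe sets, and so testing fewer, gave 20 for Pseudomonas and 142 for aphids alone. With an estimated correlation 0 lists passed for caterpillars, 0 for caterpillar minus aphid and 1 for Pseudomonas. The overlap of the insect effects, as a correlation, was 0.237 with the controls split.

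The 5' minus 3' covariate gave 2 for UV-B by caterpillar, 154 for caterpillars alone and 197 for aphids alone, with 1 list for Pseudomonas. Leaving out the 12 arrays (48 left, at least 3 a group) gave 5 for UV-B, 0 for Pseudomonas, 0 for UV-B by caterpillar, 48 for caterpillars alone and 0 for aphids alone, with 0 lists for caterpillars and 1 for Pseudomonas, and the photosynthesis median after inoculation reversed to -0.0044. COR15A then passed for both insects (0.63 and 0.64).

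Leaving out a run, or the third array with caterpillars alone, gave from 884 to 4979 for caterpillars, 913 to 4158 for aphids, 632 to 2707 for caterpillar minus aphid, 1 to 10 for UV-B, 0 to 5 for Pseudomonas, 0 to 1 for UV-B by caterpillar, 20 to 1200 for caterpillars alone and 0 to 636 for aphids alone. Lists past the threshold numbered 0 to 1 for caterpillars, 1 to 3 for aphids, 0 to 2 for caterpillar minus aphid, 0 to 2 for UV-B and 1 to 4 for Pseudomonas. Among the runs, calls of named genes were lost most often without run 2, in 39 values, and least without run 5, in 7. Without the third array with caterpillars alone 5 were lost. Signal over background was not analysed here.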

Other observations

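Families of genes that share a symbol stem, or are encoded in the plastid, were chosen after the values were available. Of 69 plastid-encoded genes measured, of photosystems, ATP synthase, ribosome and RNA polymerase of the chloroplast, 37 fell and 0 rose with aphids, with a median of log2 -0.37. Examples are psbB (-0.77, adjusted p = 0.0017), atpI (-0.74, adjusted p = 0.0041), ycf3 (-0.72, adjusted p = 0.00049) and rpoC2 (-0.71, adjusted p = 0.00031). The family's camera adjusted p was 4.8e-16, but an adjusted p of 0.45 with an estimated correlation. Its median was negative in 5 of 5 runs, from -0.435 to -0.106, and -0.37 after both a further quantile normalization (26 fallen) and centring on the median (37 fallen). With the GAPDH 5' minus 3' covariate 37 fell (median -0.34), while control probe sets for the middle (0.59) and 3' end (0.43) of Actin and the 3' end of GAPDH (0.26) rose with aphids. Whether RNA or labelling quality has a part was not decided. Fewer fell without run 1 (17), run 2 (11) or run 4 (22), without the replicate block (15) and with the 12 arrays of lowest correlation left out (14). With caterpillars 2 fell (median -0.14, camera adjusted p = 0.00054, adjusted p = 0.71 with an estimated correlation), and 12 without run 5. The 10 nucleus-encoded photosynthesis genes of the fixed list did not pass with either insect.

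Some calmodulin-like and U-box ubiquitin ligase genes fell with aphids. Of 7 calmodulin-like genes 5 fell and 1 rose (median -0.41, camera adjusted p = 0.021, adjusted p = 0.35 with an estimated correlation), and 5 and 1 did so after a further quantile normalization or centring on the median. CML37 fell with both insects (-0.88 with aphids, -0.90 with caterpillars), while CML38 fell with aphids (-0.58, adjusted p = 0.0083) and rose with caterpillars (0.49, adjusted p = 0.033), a difference of 1.06 (adjusted p = 4.3e-06). The CML38 rise was lost without run 1, 2 or 4, without the replicate block and after a further quantile normalization. With aphids the falls were 3 without run 1 and 2 without run 2. Of 9 U-box genes 4 fell, PUB19 (-1.13, adjusted p = 0.00031), PUB24 (-0.56), PUB23 (-0.56) and PUB25 (-0.45), with a median of -0.27 (camera adjusted p = 0.0056, adjusted p = 0.051 with an estimated correlation), 4 under both of those scalings and 1 without run 2. After inoculation the 6 WRKY genes had a median of 0.26 (camera adjusted p = 1.3e-05, adjusted p = 0.017 with an estimated correlation), 0.24 after a further quantile normalization and 0.27 after centring, with 0 members past the threshold. Of 46 families tested, 2 passed for caterpillars, 3 for aphids, 6 for caterpillar minus aphid, 2 for UV-B and 1 for Pseudomonas, and with an estimated correlation the 1 for Pseudomonas did.

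Genes with large insect effects also differed between runs in uninfested plants. AT5G15950 stood at 9.14, 9.88, 10.34, 8.07 and 6.58 in runs 1 to 5 without insects (means of 4 arrays), and at 7.10, 7.36, 7.23, 7.29 and 5.36 with aphids. AT1G69570 stood at 7.06, 7.58, 6.23, 5.68 and 4.66 without insects, and at 5.14, 5.19, 5.12, 4.87 and 4.39 with aphids. JAL23 without insects lay between 4.17 and 4.93 in every run, and between 6.71 and 9.33 with caterpillars.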
